A study of Mus musculus with 20 samples.

How the data were processed

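Total RNA from the myocardium of 10 male mice was measured on 10 two-colour Arraystar mouse arrays for single m6A sites, per the labels. MazF-digested, antibody-enriched RNA was labelled with Cy5 and undigested input RNA with Cy3, with equal spike-in RNA in both, per the labels' protocols. The series lists 20 samples, since the modified and input RNA of a mouse are separate samples; the deposited scans of both were identical for all 10 mice, so each mouse gave 1 array and counted once. There was no dye swap, so a dye effect and the enrichment cannot be told apart. Both genotypes had the same dye assignment, but the difference between channels was not equal on all arrays. Before dye normalization the mean spike-in log2 Cy5/Cy3 ratio was -2.09 and -1.64 in WT replicates 4 and 5, on slide 2. On slide 1 it ran from -1.29 (WT replicate 2) to 0.08 (WT replicate 1).

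The deposited scanner files hold spot intensity from Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. Their processed signal is background-subtracted and dye-normalized within the array (linear and lowess), per the file headers; this dye normalization can remove a shift shared by most sites, so the overall ratio was taken from background-subtracted signals before it. The deposited value table holds log2 values of 10004 probes, all of them on the array. Each column equalled log2 of the processed signal of its channel minus 1 constant. What the constant is and how the probes were chosen is not given in the sources used here. Its column medians were -1.51, -1.95, -1.24, -1.38 and -1.21 for Cy5 of KO replicates 1 to 5, and -1.45, -1.35, -1.34, -1.32 and -1.36 for WT. For Cy3 they were -0.84, -0.71, -0.58, -0.79 and -0.50 for KO and -0.79, -0.84, -0.56, -0.88 and -0.79 for WT.

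Groups were taken from the labels. Spots that the files flag as controls or outliers were left out, and spots of a probe were averaged. The 42 control and 24 positive control probes known only by their names stayed in; an alternative leaves them out. A probe was kept when well above background on at least 5 of 10 arrays, in both channels for the ratio. The log2 ratio of processed signals was centred on each array's median, with no loess or quantile step beyond the lowess already in the processed signal. Each single channel was scaled to the 75th percentile of its array. KO and WT were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The overall ratio was the median over kept probes minus the mean of the 65 spike-in probes (of 102, recognised by their names) well above background in both channels on at least 5 arrays, with an exact two-sided permutation test. The steps were tested on simulated data with 200 changed probes per comparison.

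Probes to name were chosen by a rule fixed before the data were examined: those with the largest changes among called probes whose groups do not overlap, or the smallest unadjusted p where fewer than 5 passed. The rule's condition of a gene name was dropped, and at most 2 probes per direction are named, after the files were seen, because 0 of the probe identifiers occur in the gene table. For the same reason the tests of 32 gene lists, which included cell type markers, and the check of the knocked-out gene could not be run. The alternatives were other filters, scalings, background corrections and blocks, the deposited value table, and leaving out each mouse. The planned normexp correction (offset 50) used median spot signals, since the files hold no mean spot signal. Its offset exceeds the median background-subtracted Cy5 signal of every array (4.09 to 17.1), so an offset of 1 was added after the data were seen. Slides and array positions come from the file headers.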

Results

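RNA methylation was measured in the myocardium of 10 male mice, 5 with a cardiac knockout of natriuretic peptide receptor A (NPRA-/-, called KO) and 5 wild type (NPRA+/+, called WT). NPRA is the cell surface receptor for atrial and B-type natriuretic peptide and makes cyclic GMP. Each mouse had 1 two-colour array whose probes each address a single N6-methyladenosine (m6A) site. The Cy5 channel held RNA that was digested with MazF, an enzyme that cuts ACA sequences lacking the methyl mark, and then enriched with an m6A antibody; this is the modified RNA. The Cy3 channel held undigested input RNA of the same mouse. The arrays carried 14408 probes with m6A site identifiers, of which 14319 had a single spot. By their names 42 of the 14408 are controls and 24 positive controls; the files do not flag them as control spots, and they were tested with the rest. The probes carry vendor identifiers that the files and the gene table used here do not pair with genes, so results are given per probe and the level of the targeted gene was not analysed here.

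The input was detected well and the modified RNA less so. On average 96.6% ± 1.35 of probes (SD, n = 5) were well above background in Cy3 in KO mice and 95.4% ± 1.66 (SD, n = 5) in WT mice. In Cy5 the means were 70.9% ± 4.21 (SD, n = 5) in KO and 61.2% ± 15.4 (SD, n = 5) in WT. This difference did not pass (exact two-sided permutation test, p = 0.238), which does not show equal detection. The 10 arrays lay on 2 slides. Slide 1 held all 5 KO mice and WT replicates 1 to 3, and slide 2 held WT replicates 4 and 5, where Cy5 detection was 48.0% and 45.2%. Within slide 1 the KO and WT means were 70.9% each (exact permutation p = 1). Array row also followed genotype on slide 1, with 4 KO mice in row 1 and 1 KO mouse with 3 WT mice in row 2. The number of arrays limits the precision.

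**Figure D1:**
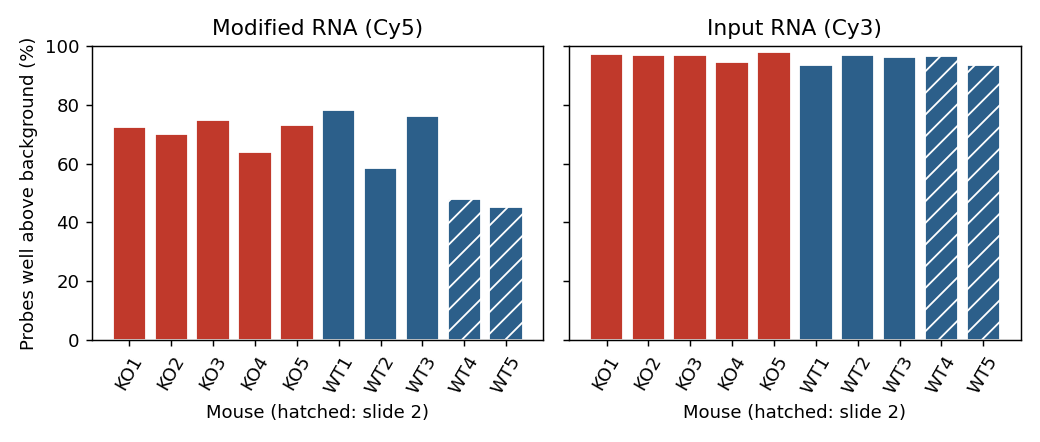
Share of site probes well above background (percent, bars from 0) for each mouse in the modified (Cy5) and input (Cy3) channel, KO in red and WT in blue, with slide 2 hatched. The slide 2 arrays have the lowest Cy5 shares, 48.0% and 45.2%.

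The first comparison asked whether the methylation level of single sites, measured as the ratio of modified to input RNA, differed between KO and WT myocardium. No site passed. Of 10056 probes tested, 0 had a limma adjusted p under 0.05, and 899 had an unadjusted p under 0.05 where 503 would be expected by chance. The smallest adjusted p was 0.104. The probes with the smallest unadjusted p, none of which passed here, were ASMM10m6ADRACA1003470104 (log2 KO minus WT -1.68, SE 0.27, limma adjusted p = 0.104) and ASMM10m6ADRACA1004646344 (-1.85, SE 0.32, limma adjusted p = 0.104) with lower values in KO. ASMM10m6ADRACA1002850744 (0.99, SE 0.22, limma adjusted p = 0.190) and ASMM10m6ADRACA1002111864 (1.12, SE 0.27, limma adjusted p = 0.202) had higher values. Of the 2 lower probes, the first was well above background in both channels in 4 of 5 KO and 5 of 5 WT arrays. The second was so in 3 of 5 KO and 4 of 5 WT arrays, so neither fall is a measured fold. The 5 KO values lay wholly above the 5 WT values at 55 probes and wholly below at 106, together 1.60% of probes against the 0.794% that chance gives. The count was 0 with slide as a block and 0 within slide 1, but the authors' deposited value table, scaled another way, called 34 sites, all lower in KO. Both named lower probes passed there (log2 -1.83 and -1.99, limma adjusted p = 0.0309 for each). Median spot signals with normexp, which replace both the dye-normalized signal and its background correction, called 3 sites, all lower, with an offset of 50, 17 (1 higher, 16 lower) with an offset of 1, and 0 with an offset of 50 followed by loess. With the offset of 50 and no loess the first named probe had a log2 change of -0.30 and the second -0.28, neither past the threshold. With the offset of 1 the first passed (-1.04, limma adjusted p = 0.0356), the second did not (-1.02, limma adjusted p = 0.130), and ASMM10m6ADRACA1002850744 passed (1.34, limma adjusted p = 0.0170). In simulated data with this spread and 200 changed probes, 44% of sites with a log2 change of 1 and 96% with a change of 2 were recovered. With fewer changed probes the adjusted threshold is stricter, and this was not simulated. These shares therefore do not exclude large changes at a few sites.

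A shift shared by all sites was measured against the spike-in RNA, which was added in equal amount to both fractions, per the labels. The median site had a spike-in-centred log2 modified/input ratio of -1.06 ± 0.05 (SD, n = 5) in KO and -0.94 ± 0.13 (SD, n = 5) in WT. The difference of -0.12 did not pass (exact two-sided permutation test over 252 assignments, p = 0.0952, adjusted over 3 such measures 0.286). Within slide 1 it was -0.07 (exact permutation p = 0.286). Over the probes well above background in both channels on all 10 arrays the difference was -0.18 (exact permutation p = 0.0317), and without WT replicate 2 it was -0.16 (exact permutation p = 0.0238), neither p adjusted over the 3 measures. Centred on all spike-in spots with a positive signal it was -0.0068 (exact permutation p = 0.913). Without spike-in centring it was 0.24, the opposite direction (exact permutation p = 0.595).

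The second comparison took the modified RNA alone, not divided by its input. At 109 of 10079 probes the Cy5 signal differed (limma adjusted p under 0.05), 19 higher and 90 lower in KO. A control probe was among the lower ones. The excess of lower sites held among called sites only: at an unadjusted p under 0.05, 945 were higher and 692 lower, and the KO values lay wholly above the WT values at 194 probes and wholly below at 188. The fitted changes of the 109 had a median size of 1.26 on the log2 scale. Among called probes whose groups did not overlap, the largest fitted rises were at ASMM10m6ADRACA1000426234 (log2 2.42, SE 0.32, adjusted p = 0.0266), and ASMM10m6ADRACA1003465334, 3.52-fold higher in KO (log2 1.82, SE 0.30, adjusted p = 0.0266). The first was well above background in 5 of 5 KO and 3 of 5 WT arrays, so its fitted change is not a measured fold. In the same set the largest fitted falls were at ASMM10m6ADRACA1003386894 (log2 -3.22, SE 0.55, adjusted p = 0.0292) and ASMM10m6ADRACA1003470104 (log2 -2.01, SE 0.31, adjusted p = 0.0266). The former was well above background in 1 of 5 KO and 5 of 5 WT arrays and the latter in 4 of 5 KO and 5 of 5 WT arrays, so neither is a measured fold. In the ratio these 4 probes, in the order named, changed by 0.61, -0.16, -1.62 and -1.68, none past the threshold. The rise of ASMM10m6ADRACA1003465334 was of similar size in its input (log2 1.89). The Cy5 sizes differed with median spot signals and normexp, which change the signal and its background correction together. At an offset of 50, ASMM10m6ADRACA1000426234 changed by 0.28 (adjusted p = 0.415), ASMM10m6ADRACA1003465334 by 1.17 (adjusted p = 0.101), ASMM10m6ADRACA1003386894 by -0.40 (adjusted p = 0.260) and ASMM10m6ADRACA1003470104 by -0.57 (adjusted p = 0.120). At an offset of 1 these were 1.26, 1.80, -1.13 and -1.37, all past the threshold. With slide and array row as a block, which leaves 1 KO mouse against 3 WT mice, they were 1.71, 1.08, -3.05 and -1.80. The errors were larger there (SE 0.44, 0.43, 1.04 and 0.57), and the calls were not kept. The count rested on single mice: 0 sites were called without KO replicate 5, and 1 each without KO replicate 1 (lower) or WT replicate 1, 3 or 4 (higher). Without both mice numbered 3, 11 were higher and 13 lower. The count was 63 without KO replicate 2, 53 without KO replicate 3 and 68 without WT replicate 5. The changes of the 4 named probes kept about their size where calls were lost. In the order named they were 2.40, 1.79, -2.99 and -2.06 without KO replicate 5, and 2.40, 1.71, -3.30 and -1.91 without WT replicate 1. With slide as a block 16 sites were higher and 361 lower, and within slide 1 21 and 355. These calls held 69 and 70 of the 109. Spike-in scaling called 0 sites and no filter on dim probes 0. The named changes stayed at 2.36, 1.75, -3.28 and -2.07 with spike-in scaling (limma adjusted p 0.0636 to 0.0861). They were 2.42, 1.82, -3.22 and -2.01 with no filter (limma adjusted p = 0.0586 for each). Normexp with an offset of 50 called 1 site, which was higher. With an offset of 1 it called 8 higher and 124 lower.

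The third comparison took RNA abundance in the input. Of 13941 probes, 232 differed (limma adjusted p under 0.05), 86 higher and 146 lower in KO. Among called probes whose groups did not overlap, the largest rises were at ASMM10m6ADRACA1003465334, 3.71-fold higher in KO (log2 1.89, SE 0.19, adjusted p = 0.000948), and ASMM10m6ADRACA1000426234, 3.31-fold higher (log2 1.73, SE 0.16, adjusted p = 0.000948). The largest falls in that set were at ASMM10m6ADRACA1004917794, 5.63-fold lower (log2 -2.49, SE 0.26, adjusted p = 0.00146), and ASMM10m6ADRACA1002072844, 3.73-fold lower (log2 -1.90, SE 0.32, adjusted p = 0.0187). With slide and array row as a block, which leaves 1 KO mouse against 3 WT mice, all 4 calls were lost (adjusted p = 0.158, 0.155, 0.246 and 0.937), with log2 changes of 1.99, 1.96, -2.60 and -1.83 and larger errors (SE 0.33, 0.29, 0.49 and 0.63). With slide alone as a block the first 3 held (adjusted p = 0.00439, 0.00477 and 0.00477) and the fourth was lost at a log2 change of -1.78 (SE 0.38, adjusted p = 0.0905). Spike-in scaling lost the third at -2.28 (SE 0.34, adjusted p = 0.0511) and the fourth at -1.68 (SE 0.33, adjusted p = 0.117). The fourth was lost in 8 of 25 settings, among them without KO replicate 2 (adjusted p = 0.0561) and without WT replicate 4 (adjusted p = 0.0534). A control probe was among the higher ones. Quantile normalization called 165 higher and 124 lower, and spike-in scaling 4 higher and 0 lower, so the count and balance depend on the scaling.

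KO replicate 3 and WT replicate 3 did not follow their groups in the input, which was examined after the calls were seen. Without WT replicate 3 the count was 1046, without KO replicate 3 it was 583, and without both it was 2334 (680 higher and 1654 lower in KO), which held all 232 sites. At the 200 sites with the smallest p in the other 8 mice, on a scale where the mean of those WT mice is 0 and of those KO mice is 1, the input of KO replicate 3 lay at a median of 0.0297 and that of WT replicate 3 at 0.609. In Cy5, at sites chosen the same way, they lay at 0.609 and 0.288. Without both mice the 4 named input probes had log2 changes of 1.99 (ASMM10m6ADRACA1003465334), 1.75 (ASMM10m6ADRACA1000426234), -2.37 (ASMM10m6ADRACA1004917794) and -1.77 (ASMM10m6ADRACA1002072844), all past the threshold. Without any other mouse the count fell to between 43 and 117, and it was 27 with slide as a block and 26 within slide 1, where fewer mice enter the contrast.

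**Figure D2:**
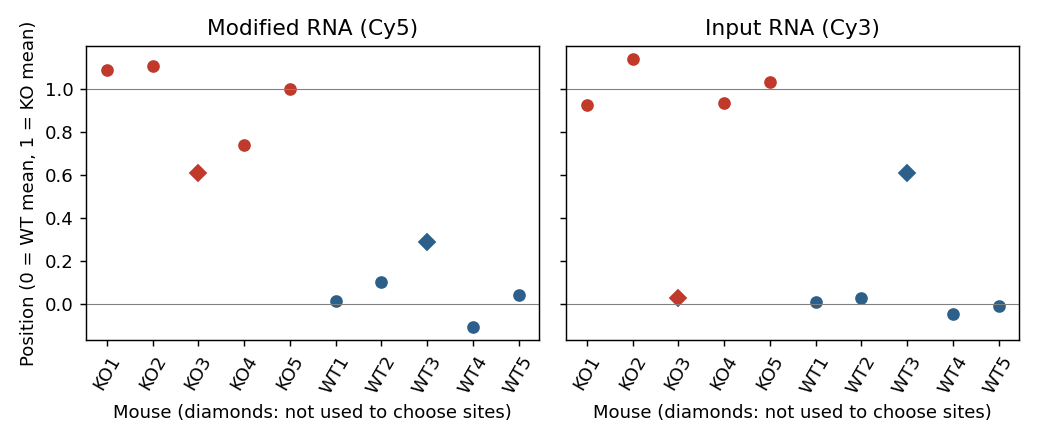
Position of each mouse in the modified (Cy5) and input (Cy3) channel, as the median over 200 sites chosen in the 8 mice drawn as circles, on a scale with the mean of those WT mice at 0 and of those KO mice at 1. In the input KO replicate 3 (red diamond) lies at 0.0297 and WT replicate 3 (blue diamond) at 0.609.

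**Figure D3:**
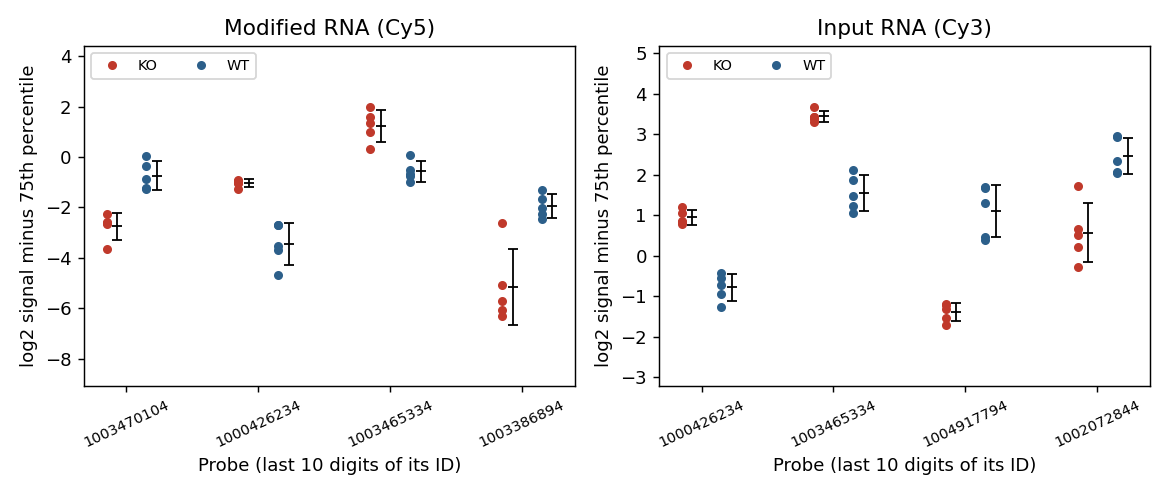
Scaled log2 signal of each mouse (points) at the probes with the largest rises and falls among called probes whose groups do not overlap, for modified and input RNA, with the mean and SD of each group (black, n = 5) and KO in red, WT in blue. The KO and WT points do not overlap at any of these probes.

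The changes in both channels ran in parallel. Among 10071 probes tested in both, 11 sites were higher in both and 13 lower in both, where independent lists, which share no arrays, would hold 0.134 and 0.840 in common, and 0 were called in opposite directions. Of the 109 sites called in the modified RNA, 106 had the same sign in the input. The 90 lower sites had a median log2 change of -1.27 in Cy5 and -0.58 in the input. Across probes, which are not independent replicates, the changes correlated with r = 0.642 (covariance 0.0821). Both channels come from the same mice and arrays, so part of this correlation arises with no genotype effect. Shared calls may arise so too, but they were not counted over other splits. In 99 other splits of the mice the median r was 0.485 and the highest 0.660, and the median covariance was 0.0280 and the highest 0.0838. Of 100 splits, the labelled one included, 4 had an r and 2 a covariance as high as the labelled one.

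**Figure D4:**
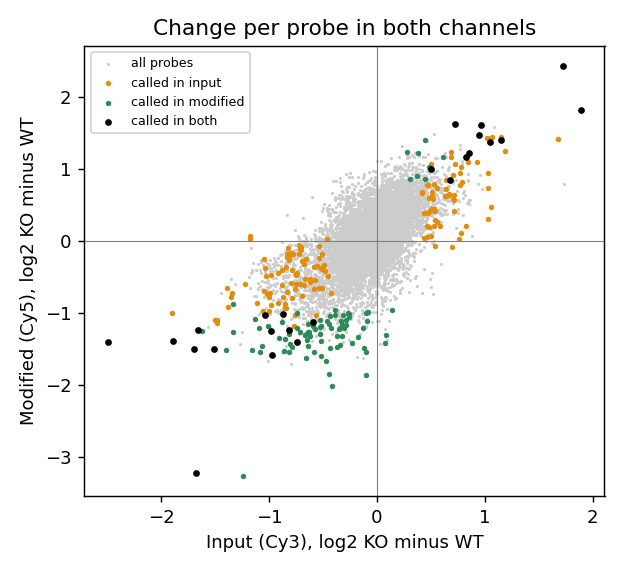
Log2 change (KO minus WT) of each probe in the input (horizontal axis) and in the modified RNA (vertical axis), with called sites coloured. Of the sites called in both channels, 11 lie in the upper right and 13 in the lower left.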

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

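The tests of slide 2 for the modified RNA, of its direction over other splits, of normexp with an offset of 1, of array column, of an exchange in the input, and of slide 2 at input sites chosen by size were chosen only after the result was seen. Of 34 groups of 5 mice tested, 2 held a mouse far from the others, about what chance gives, since it flags 5% of groups. In WT, replicate 3 had an input level relative to spike-in of 0.37 (log2), against -0.06 for the nearest mouse. At ASMM10m6ADRACA1003470104 the scaled Cy5 signal of KO replicate 1 was -3.65, against -2.64 for the nearest KO mouse.

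The input calls depended on the mice numbered 3. Chance is argued against, though not excluded, for the count of 232, which 2 of 100 splits of the mice reached, the labelled one included. The labelled split partly follows slide and array row, so its rank does not tell genotype from layout. The other split gave 2823 sites and differs only by exchanging KO replicate 3 and WT replicate 3. A split with several times the labelled count points to a structure among these mice. Slide 2 is argued against as the whole cause, since the change within slide 1 was 98.1% of the pooled change (95% bootstrap interval over sites 96.8 to 99.4). Calling favours sites where the WT mice of both slides are close, but over all 428 sites with a log2 change of at least 0.74, called or not, it was 100.1% (interval 98.1 to 103.4), with 2 sites under 50%. Array row stays open: of 200 sites chosen on row 1, 26.5% had the same direction in row 2, but row 1 sets KO mice on slide 1 against WT mice on slide 2, and the 1 KO mouse in row 2 is KO replicate 3, so this value decides nothing about row. At 200 input sites chosen in the other 8 mice, 19% differed between the mice numbered 3 in the direction of the labels, as an exchange in the input would give. The other same-numbered pairs, treated the same way, gave 86.5% to 98%. For Cy5 61.5% did (interval over sites 54.4 to 68.3), below the 76.5% to 94% of the other pairs. This argues against an exchange of both fractions, but only weakly, since sites are not independent and 1 mouse per genotype enters. Most called sites went the other way. Of the 232, 212 had KO and WT values that did not overlap, the mice numbered 3 included. At ASMM10m6ADRACA1003465334 KO replicate 3 had a scaled input of 3.38 (KO range 3.30 to 3.67). WT replicate 3 had 1.88 there (WT range 1.05 to 2.11). At ASMM10m6ADRACA1004917794 these mice had -1.33 and 1.68, also on their labelled sides. An input exchange would not give this, but calling with the labels favours such sites. An exchange of the input alone, RNA or tissue differences unrelated to genotype, and a genotype effect that these mice do not share remain open. Array position stays open for them too, since WT replicate 3 shares an array column with KO replicate 5. The groups were kept as labelled.

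Among the sites called in the modified RNA, more were lower than higher in KO. Chance is argued against, though not excluded, for the count of 109, which 1 of 100 splits, the labelled one, reached, with 10 the highest of the others. The labelled split partly follows slide and array row, so its rank does not tell genotype from layout. For a direction beyond the called sites chance stays open: at an unadjusted limma p under 0.05, 42.3% were lower, and 69 of 100 splits were as uneven. Slide 2 is argued against as the whole cause by 94.4% of called sites being lower within slide 1, though those calls held only 70 of the 109. Dim probes as the whole cause are argued against by 82.1% (interval over sites 76.1 to 87.1) being lower among probes well above background on all 10 arrays. Those calls held 83 of the 109. The signal and its background correction stay open. Median spot signals with normexp called 1 site, a higher one, with an offset of 50. With an offset of 1 they called 8 higher and 124 lower. No filter on dim probes called 0 sites over 14407 probes, but it changes neither the signal nor its correction. There the named Cy5 changes stayed at 2.42, 1.82, -3.22 and -2.01, so that count says nothing about this cause. Lower RNA abundance stays open as part of the cause, as do array row and genotype: the median input change was 46.1% of the Cy5 change (bootstrap interval 36.7 to 52.0), which does not clear the bound of 50%, and 67.5% of 200 Cy5 sites chosen on row 1 (interval over sites 60.5 to 73.9) had the same direction in row 2, with the limits given for the input.

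KO replicate 5 and WT replicate 3 deviated together in the input, with r = 0.786 across probes, which are not independent. A shared array column stays open: the other pairs within a column correlated at 0.0493, 0.182 and, for KO replicates 3 and 4, 0.329. Array brightness is argued against, since r was 0.779 after quantile normalization. No biological explanation was tested.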

How the results depend on the processing

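The settings within slide 1, with slide and array row as a block, without both mice numbered 3, without probes named as controls, with a normexp offset of 1 and with all spike-in spots were chosen after seeing the data. The cause of each change below was not tested, except that fewer mice or other probes enter where a setting leaves them out. For the ratio, the deposited value table called 34 sites, normexp 3, and leaving out both mice numbered 3 gave 1, all lower in KO; normexp with an offset of 1 called 17; leaving out 1 mouse gave 0 to 1, and all other settings 0. For the modified RNA, the count of 109 became 377 with slide as a block, 376 within slide 1, 201 over probes well above background on all 10 arrays, 187 with trend and robust eBayes and 172 with the deposited table. Of the 109 sites themselves, these calls held 69, 70, 83, 101 and 100. The sites called without both mice numbered 3 held 14 of the 109. With slide and row as a block, which leaves 1 KO mouse against 3 WT mice, the called sites were not among the 109. The site called by normexp with an offset of 50 was not among the 109 either. The counts changed further in these and other settings. They became 24 without both mice numbered 3, 7 with slide and row as a block, 1 with normexp, and 0 with no filter or with spike-in scaling; leaving out 1 mouse gave 0 to 145. For the input, 232 became 2334 without both mice numbered 3, 27 each with slide as a block, the deposited table (15 higher, 12 lower) and normexp (14 higher, 13 lower), 121 with a normexp offset of 1, 26 within slide 1, 4 with spike-in scaling (all higher) and 2 with slide and row as a block, which leaves 1 KO mouse against 3 WT mice; leaving out 1 mouse gave 43 to 1046. Spike-in scaling moved the median input change from -0.06 to 0.15. The overall ratio of -0.12 became -0.18 over probes well above background on all 10 arrays (exact permutation p = 0.0317) and 0.24 uncentred, and leaving out 1 mouse gave -0.156 (without WT replicate 2, exact permutation p = 0.0238) to -0.0771; none of these p is adjusted over the 3 measures. With all spike-in spots it was -0.0068 (exact permutation p = 0.913). Leaving out probes named as controls gave 0, 107 and 238 sites for the ratio, the modified RNA and the input.

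The replicate numbers did not pair the mice: deviations of same-numbered mice correlated at -0.154 to 0.207 in the ratio, -0.186 to 0.0967 in the modified RNA and -0.247 to 0.182 in the input, and 1, 0 and 0 of 10 mice correlated best with their own number. With the replicate block the counts were 0 for the ratio, 0 for the modified RNA and 10 for the input, and the overall ratio was -0.12. The gene list tests and their alternatives were not run, because the files pair no probes with genes. Signal over background limits the modified RNA, with 45.2% of probes well above background on the dimmest array.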

Other observations

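Spots of a probe repeated 10 times on an array differed less than the arrays of different mice did. Over 36 tested probes with 10 spots, the median SD of the log2 ratio was 0.133 between spots of an array and 0.324 between mice of a group. Each mouse had 1 array, so the second value also holds differences of digestion, enrichment, labelling and array. Most probes had a single spot, so these 36 need not stand for the rest.

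The excess of small unadjusted p-values for the ratio is within what other groupings of the mice give. As labelled, 899 sites had an unadjusted p under 0.05, and 14 of 100 splits gave as many, with a highest of 1413, so chance cannot be excluded for that count.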
